A study of Mus musculus with 201 samples.

How the data were processed

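Hippocampal RNA from 201 pooled samples of 100 mouse strains was hybridized to Affymetrix M430 2.0 arrays with 45101 probe sets. Of these, 64 control probe sets were left out and 45037 were tested. The annotation gave 1 gene symbol to 34945 tested probe sets, several to 932 and none to 9160, for 18193 different symbols. Genes were named from probe sets with 1 symbol.

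The authors deposited PDNN, RMA and MAS5 summaries as a score per probe set and array, and raw intensities were not used here. PDNN values are deposited scores on a log-like scale whose base is not given in the sources used here. They were therefore analysed as deposited, differences are given in PDNN units, and no fold changes were computed. Per the labels each PDNN array was scaled to a mean of 8 and an SD of 2, but the arrays had means of 8.06 to 8.10 and SDs of 0.633 to 0.801. The RMA and MAS5 scores deposited by the authors had a mean of 8 and an SD of 2 in every array. The value table of the series held the same PDNN scores, with 0 cells that differed. The RMA table held 197 arrays. Software versions of the authors are not given in the sources used here. Values ran from 6.50 to 12.7 PDNN units, and arrays have no counting depth.

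Groups came from the strain, sex, age and batch labels. The file headers of 7 arrays disagreed with the labels in strain (4 arrays), sex (3) or batch (1), and 8 more arrays carried former names of BXD strains. Labels were used throughout. A B6D2F1 male array labelled as a technical duplicate was averaged with the other B6D2F1 male array. The 1 array of mixed sex, BXD9 replicate 2, was left out. This gave 199 columns, 107 model terms and 92 residual degrees of freedom, with a median residual SD of 0.0782 units. Arrays were processed in 7 batches of 25 to 32, and of 95 strains with at least 2 arrays 92 were spread over more than 1 batch.

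A linear model with strain, sex and batch was fitted to every probe set with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8). Strain contrasts used limma's moderated test with the spread shared over all strains. Strain effects within the BXD and CXB panels used limma's moderated F-test with sex and batch as covariates, and an intraclass correlation described their size. The sets of strains, wild-derived against classical and later against earlier BXD, were compared between strain values in a second limma fit, so that strains were the replicates. Sex was tested across strains and, as an interaction, between the BXD, CXB and inbred panels. Age was tested as a slope per 10 days of mean pool age. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all probe sets, and the threshold was an adjusted p of 0.05.

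The 20 gene lists, the comparisons, the tests, the rule for named genes and most alternative settings were chosen before the data were examined. The lists were known strain variants, Y-linked genes, genes of X inactivation and escape, pyramidal neurons, dentate granule neurons, interneurons, oligodendrocytes and myelin, astrocytes, microglia, endothelium, choroid plexus, thalamus, erythroid genes, immediate early genes, adult neurogenesis, GABA-A receptors, ionotropic glutamate receptors, MHC class I and interferon-response genes, the respiratory chain and ribosomal proteins. Each gene was represented by its probe set with the highest mean. Lists were tested in 5 comparisons with limma's camera at its preset inter-gene correlation of 0.01 and again with an estimated correlation. Members were counted over all probe sets and adjusted over the list alone.

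Named genes were the 10 largest rises and 10 largest falls among calls with 1 symbol that is not a clone or predicted-gene name, through the probe set with the largest difference. For strain effects they were the 20 with the largest SD of strain means. Members of the lists were named as well, those of the known strain variants through every probe set.

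The alternatives were RMA values, MAS5 values, the series value table, a filter on a mean of 8 or more, quantile normalization, no batch term, age as a covariate, removal of arrays with an RMA outlier share of 0.1 or more, of pools older than 100 days and of each compared array or strain, separate use of the duplicate, averaged substrains, spread from inbred strains and F1 hybrids alone, the BXD panel alone for the sex comparison, the animal source as a covariate, and an estimated correlation. For results over whole panels, 20 arrays drawn with a fixed seed were each left out. Alternatives chosen after seeing the data were removal of arrays with disagreeing headers, rescaling to an SD of 2, the first or the first 4 components of the variation within BXD strains as covariates, RMA values without mismatched columns, the choroid plexus mean as a covariate, and strains of the most frequent source alone. For each comparison of sets, 99 random splits were drawn beside the real one.

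The models were tested on simulated data with 200 probe sets changed per comparison. A difference of 0.4 units was recovered for 80.6% of changed probe sets between DBA/2J and C57BL/6J, 98.5% between F1 hybrids and the mid-parent, 79.1% between reciprocal F1 hybrids, 70.1% between C57BL/6J and C57BL/6ByJ, and 94.0% between wild-derived and classical strains. A difference of 0.1 units was recovered for 92.5% between the sexes and 76.1% between later and earlier BXD strains. A strain SD of 0.2 units was recovered for 97.0% in the BXD and 62.7% in the CXB panel. An age slope of 0.05 units was recovered for 96.0%, and a sex difference between panels of 0.2 units for 84.0%. False calls numbered 1 to 15 per comparison among 45037 probe sets. The simulated noise was drawn independently for each probe set, so variation that probe sets of an array share was left out. In the real BXD arrays the first component of such variation held 21.7% of the residual variance. False calls from shared variation were therefore not measured.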

Results

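The data were hippocampal RNA profiles of 100 strains of mice, measured on 201 Affymetrix M430 2.0 arrays. Most strains were represented by 1 pool of males and 1 pool of females. The BXD strains are recombinant inbred lines descended from C57BL/6J and DBA/2J, so that each line fixed a different mixture of the alleles of both parents. The earlier BXD set held 29 strains on 58 arrays and the later set held 39 strains on 76 arrays. The CXB strains, recombinant inbred lines from BALB/cByJ and C57BL/6ByJ, numbered 13 on 27 arrays. A further 13 classical inbred strains were on 27 arrays, 4 wild-derived inbred strains were on 7, and the reciprocal F1 hybrids B6D2F1 and D2B6F1 were on 6. The labels gave 101 arrays as female, 99 as male and 1 as mixed. Pools held 1 to 4 mice with a median of 3, and mean pool age ran from 41 to 196 days with a median of 62. The labels do not say whether arrays of a strain came from separate animals, so p-values measure the spread between pooled samples. The share of probe sets called present ran from 43.3% to 55.3% with a median of 50%. The small number of arrays per strain limits the precision of single strains.

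Across the BXD panel, the question was which hippocampal transcripts differ from strain to strain. The widest spread among genes named by the fixed rule was that of Prune2, which ran from 7.37 PDNN units in BXD74 to 10.24 in BXD23, with an SD of strain means of 0.974 units. Snhg14, the host of small nucleolar RNAs in the imprinted Prader-Willi region, had an SD of 0.909, and Cap1, a regulator of actin filaments, had an SD of 0.863. Pttg1, the securin that restrains chromosome separation, ran from 8.26 units in BXD67 to 10.25 in BXD76 with an intraclass correlation of 0.964. Phgdh, the first enzyme of serine synthesis, ran from 7.89 units in BXD86 to 9.69 in BXD73a with an intraclass correlation of 0.967. Prdx2, a peroxide-removing enzyme, had an intraclass correlation of 0.969, and Pdxdc1, a protein with a pyridoxal-dependent decarboxylase domain, had 0.973.

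The other genes of the BXD strain effect were Rpgrip1, a protein of the photoreceptor cilium, Gnb1, a G protein beta subunit, and Sox11, a transcription factor of immature neurons. The rule also took Fam126b, Stk25, Pisd-ps3, Rps9, Mtmr7, Fam168a, Gprc5b and Snhg11. Ecrg4 and Clic6, both abundant in choroid plexus, had lower intraclass correlations of 0.431 and 0.382. In all, 3773 of 45037 probe sets (8.378%) passed limma's F-test across 68 strains and 133 arrays, which covered 2462 genes. The median intraclass correlation was 0.476 among the calls and 0.0601 among all probe sets. With MAS5 values the count was 2458, and among probe sets with a mean of 8 or more it was 2260.

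In the CXB panel, Prune2 again had the widest spread of the named genes, from 7.22 units in CXB11 to 9.60 in CXB12, with an SD of strain means of 1.021. Pisd-ps3, a pseudogene of a phosphatidylserine decarboxylase, had an SD of 0.983, Cap1 had 0.943 and Rpgrip1 had 0.884. Pttg1, Phgdh, Pdxdc1, Rps9, Prdx2, Sox11, Stk25 and Mtmr7 were named in both panels. Arl2bp, a binding partner of a small GTPase, passed in the CXB panel with an SD of 0.571, and its adjusted p in the BXD panel was 0.891. Uqcr10, a subunit of respiratory complex III, passed in the CXB panel with an SD of 0.546, and its adjusted p in the BXD panel was 0.478. No test of the difference between panels was run for either gene. The rule also took Efhd2, Erdr1, Rasal2, Mir1931, Arhgap26 and Ptp4a2.

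Of 45037 probe sets, 492 (1.092%) passed limma's F-test across 13 CXB strains and 27 arrays, and they covered 329 genes. Of these calls, 319 (64.84%) were also calls in the BXD panel, against 41.22 by chance. The CXB count was 212 with MAS5 values, 315 among probe sets with a mean of 8 or more, and 172 without arrays whose labelled RMA outlier share was 0.1 or more.

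Among the gene lists fixed before the data were examined, the choroid plexus list had the highest share of members with a BXD strain effect, at 9 of 10 measured. Its members Folr1, Kl and Cldn2 had adjusted p of 0.00329, 0.000844 and 0.00189, while Ttr, the thyroid hormone carrier, had an adjusted p of 0.372. The members varied together, with an estimated correlation of 0.856 in the list test between DBA/2J and C57BL/6J, so they are not separate findings. Their median intraclass correlation was 0.408, against 0.757 for the known strain variants. Whether the amount of choroid plexus in the dissected tissue differed between strains was not tested. Of the genes known before for strain variants, 8 of 10 passed, among them Pam, an enzyme that amidates peptides, with an intraclass correlation of 0.931, and Alad, an enzyme of haem synthesis, with 0.921. Among MHC class I and interferon-response genes, 7 of 11 passed in the BXD panel and 7 of 11 in the CXB panel, where H2-D1 had an intraclass correlation of 0.928 and Ifit1 had 0.924. Of the dentate granule neuron markers 5 of 10 passed, and C1ql2, a secreted protein of mossy fibre synapses, had an intraclass correlation of 0.905.

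The remaining lists had smaller shares with a BXD strain effect. These were 4 of 11 pyramidal neuron markers, 2 of 12 interneuron markers, 4 of 11 myelin genes, 2 of 10 astrocyte markers, 4 of 11 microglia markers and 3 of 9 endothelial markers. Of thalamus markers 1 of 10 passed, of erythroid genes 1 of 3, of immediate early genes 4 of 12 and of neurogenesis genes 1 of 14. Among receptor subunits 2 of 9 GABA-A and 4 of 12 ionotropic glutamate receptor genes passed, and 3 of 12 ribosomal protein genes did. None of the 3 Y-linked genes, the 5 genes of X inactivation and escape, or the 16 respiratory chain genes passed limma's test, in a panel with 7949 probe sets at an unadjusted p under 0.05.

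The comparison of DBA/2J against C57BL/6J asked how the parents of the BXD panel differ. Gas7, which takes part in neurite outgrowth, was higher in DBA/2J by 2.18 ± 0.60 PDNN units (SE; 2 arrays against 3), and Cap1 was higher by 2.03 ± 0.25 units. Slc1a2, the main glial glutamate transporter, was higher by 1.74 ± 0.34 units at 1 probe set, and 1 of its 4 further probe sets was called higher as well (0.355 ± 0.105), while its brightest probe set differed by 0.0316 ± 0.135. Phgdh was lower in DBA/2J (difference -1.53 ± 0.15 units, adjusted p = 1.0e-13), and Pttg1 differed by -1.44 ± 0.15 units. Gfap, the intermediate filament protein of astrocytes, differed by -1.16 ± 0.26 units.

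Also higher in DBA/2J were Ptp4a2, a tyrosine phosphatase (1.96 ± 0.30 units), Sfpq, a splicing factor (1.72 ± 0.48), Slc8a1, a sodium-calcium exchanger (1.71 ± 0.30), and Gsk3b, a kinase of Wnt signalling (1.71 ± 0.38). Chic1 (1.66), Rbfox2, a splicing regulator (1.65), and Malat1, an abundant nuclear RNA (1.63), were also higher. Lower in DBA/2J were Prune2 (-1.41 ± 0.31 units), Erdr1 (-1.35 ± 0.21), Mt3, the metallothionein of neurons (-1.31 ± 0.26), Snhg11 (-1.21 ± 0.15) and Rpgrip1 (-1.21 ± 0.24). Rps9, a ribosomal protein, differed by -1.15 ± 0.14 units, and Mtmr7, a phosphoinositide phosphatase, by -1.14 ± 0.12. Prune2 was lower at 1 probe set, while 2 of its 3 further probe sets were called higher in DBA/2J. Of 19 named genes with further probe sets, 8 had none of them called the same way (Gas7, Ptp4a2, Rbfox2, Prune2, Erdr1, Snhg11, Rpgrip1 and Rps9). The probe sets of Sfpq, Rbfox2, Gsk3b and Slc8a1 were among those leading component 3 of the variation within BXD strains. On component 3 the C57BL/6J arrays scored -1.07, -2.13 and -2.74 SD and the DBA/2J arrays 2.155 and 0.677. The Gas7 probe set led component 2. With the first 4 components as covariates, 5 of the 20 named genes lost their call.

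Myelin genes were lower in DBA/2J as a group. Of 11 measured members 8 fell (10 when adjusted over the list alone), with Mal at -0.838 ± 0.173 units, Mag, a myelin adhesion protein, at -0.794 ± 0.147, Mobp at -0.733 ± 0.155 and Mog at -0.635 ± 0.152. Cldn11, Cnp, Ermn and Opalin also fell, and Mbp, Ugt8a and Gjb1 did not pass the test. The list's adjusted p in limma's camera test was 2.8e-10, and the adjusted p = 0.0389 with an estimated correlation. The median ACTB 3'/5' ratio, a sign of RNA length, was 1.67 in the C57BL/6J arrays and 1.29 in the DBA/2J arrays, and the median share of probe sets called present was 47.7% and 51.4%.

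Genes known before for strain variants were higher in DBA/2J, with 5 of 10 past the test (7 higher and 1 lower when adjusted over the list alone; adjusted p = 8.7e-08, and adjusted p = 1.3e-05 with an estimated correlation). Gabra2, a GABA-A receptor subunit, was higher by 0.942 ± 0.098 units, Pam by 0.792 ± 0.094, Alad by 0.534 ± 0.101 and Glo1, which detoxifies methylglyoxal, by 0.474 ± 0.133. Kcnj9, a potassium channel, was higher by 0.626 ± 0.119 units at its brightest probe set and differed by -0.344 at another. Of the 5 genes of X inactivation and escape, Kdm6a (0.434 ± 0.107) and Ddx3x (0.490 ± 0.127) rose, also 2 when adjusted over the list alone (list adjusted p = 0.00508, and adjusted p = 0.0285 with an estimated correlation). Both DBA/2J arrays were labelled female and C57BL/6J replicates 2 and 3 male, so this list call leans on the fitted sex term. Between males and females across strains, Kdm6a differed by -0.180 and Ddx3x by -0.146 units. Of 9 GABA-A receptor subunits Gabra2 and Gabrb1 rose, and 4 when adjusted over the list alone. The list had an adjusted p of 0.00225 and lost its call with an adjusted p = 0.153 with an estimated correlation.

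In the other lists single members passed, and the lists themselves did not. C1ql2 (-0.678 ± 0.111 units) and Tdo2 (-0.376 ± 0.109) fell among 10 dentate granule markers, and Dcx, a microtubule protein of immature neurons, rose by 0.584 ± 0.172 among 14 neurogenesis genes. Slc1a3 rose by 0.326 ± 0.109 units and Gfap fell among 10 astrocyte markers, Cx3cr1 rose by 0.355 ± 0.113 among 11 microglia markers, and Esam (-0.181) and Slco1a4 (-0.223) fell among 9 endothelial markers. Bok (-0.292), Prkcd (-0.318) and Rps6 (-0.440) were the single members to pass among pyramidal neuron, thalamus and ribosomal protein genes. No member passed limma's test among the Y-linked, interneuron, choroid plexus, erythroid, immediate early, glutamate receptor, MHC and interferon, or respiratory chain genes, with 7777 probe sets at an unadjusted p under 0.05. The mean, the median and the direction of the test differed in sign for the astrocyte, thalamus, erythroid and respiratory chain lists.

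Altogether 3259 of 45037 probe sets passed limma's test between the parents, 2072 higher and 1187 lower in DBA/2J (63.58% higher), and they covered 1899 genes with a median absolute difference of 0.376 units. Of the calls, 1089 (33.42%) were also BXD strain effects, against 273 by chance. That share was 16.7% for calls higher in DBA/2J (346 of 2072, 173.6 by chance) and 62.59% for calls lower in DBA/2J (743 of 1187, 99.44 by chance). The SD of the BXD strain means, divided by 0.5 times the parental difference, had a median of 0.486 over all parental calls.

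**Figure D1:**
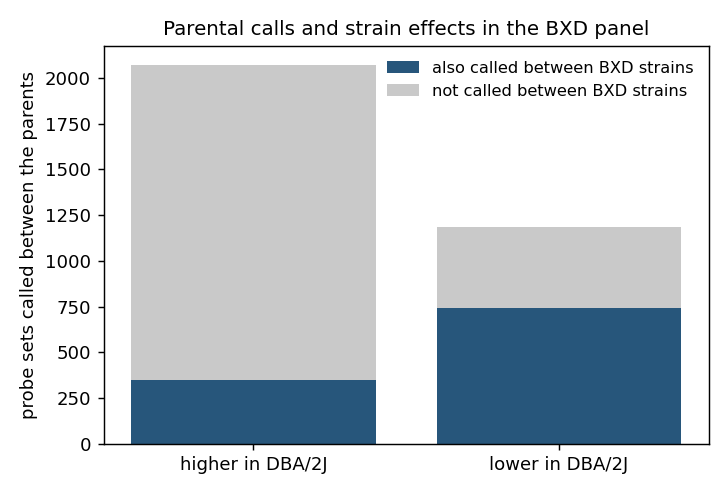
Probe sets called between DBA/2J and C57BL/6J (y axis, number), split into calls higher and lower in DBA/2J (x axis), with those also called between BXD strains in blue and the others in grey. Of the calls higher in DBA/2J 346 of 2072 were BXD calls, and of those lower 743 of 1187.

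The count for DBA/2J against C57BL/6J depended on single arrays and on the model. Leaving out DBA/2J replicate 1, DBA/2J replicate 2 or C57BL/6J replicate 2 gave 1429, 2141 or 1899 calls, no batch term gave 1480, spread from inbred strains and F1 hybrids alone gave 880, a mean of 8 or more gave 2130, and the first residual component as a covariate gave 4995. With the first 4 residual components as covariates there were 2178 calls, of which 1132 were among the 3259 and 47.66% were higher in DBA/2J. The deposited RMA table gave 2016 calls, 41.27% higher, and turned the direction of Phgdh, Pttg1, Prune2 and Rpgrip1, but its 3 columns headed C57BL/6J correlated across probe sets with the BALB/cJ arrays at 0.944 to 0.962 and with their own at -0.0816 or less.

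The F1 hybrids were compared with the mean of their parents to ask whether any transcript departs from the mid-parent level. No probe set passed limma's test of the F1 hybrids against the mid-parent, with 1348 at an unadjusted p under 0.05 and a smallest adjusted p of 0.105. The count was 3 without D2B6F1 replicate 1, 1 without B6D2F1 replicate 2, 4 with quantile normalization, 1 with MAS5 values, and 162 with RMA values, whose C57BL/6J columns matched other arrays.

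The reciprocal F1 hybrids carry the same autosomal alleles but have opposite mothers and fathers, so their difference addresses parent-of-origin effects. By the labels 2 of the 3 B6D2F1 arrays were male and all 3 D2B6F1 arrays female, so the sex chromosomes differ as well. Snhg14 was higher in D2B6F1, whose father was C57BL/6J, than in B6D2F1 by 2.15 ± 0.22 PDNN units (SE; 3 arrays each, 2 of the B6D2F1 arrays averaged; adjusted p = 3.2e-11). Its fitted level was 10.0 units in D2B6F1 and 9.68 in C57BL/6J, and 7.84 in B6D2F1 and 8.63 in DBA/2J. The pair of averaged B6D2F1 arrays, replicates 2 and 3, had values of 7.68 and 8.69, the latter above both DBA/2J arrays (8.535 and 8.474). A probe set listed with both Snurf and Snrpn, which lie in the same imprinted region, was higher by 1.30 ± 0.15 units (adjusted p = 8.6e-09). Its fitted levels were 8.64 in D2B6F1, 8.65 in C57BL/6J, 7.34 in B6D2F1 and 7.18 in DBA/2J. A probe set without a gene symbol was higher by 0.524 ± 0.102 units (adjusted p = 0.0207).

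**Figure D2:**
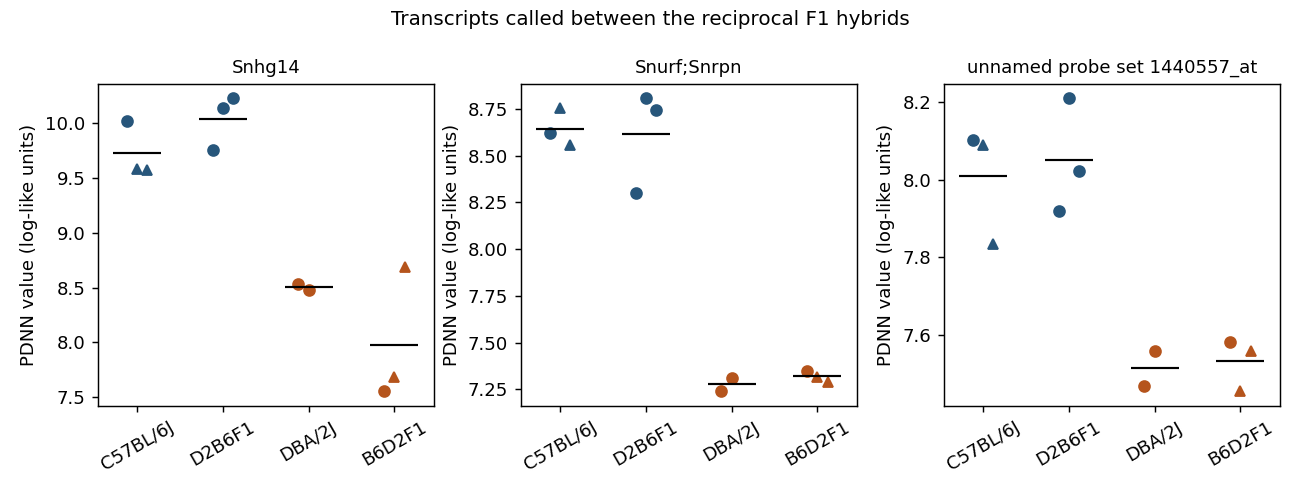
PDNN values (y axis, log-like units) of each array at the 3 probe sets called between the reciprocal F1 hybrids, for C57BL/6J, D2B6F1, DBA/2J and B6D2F1 (x axis), with bars at the means and circles for female and triangles for male arrays. The D2B6F1 arrays lie near C57BL/6J and the B6D2F1 arrays near or below DBA/2J.

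These 3 probe sets, all higher in D2B6F1, were the only calls of limma's test, with 1097 at an unadjusted p under 0.05. Snhg14 had 2 further probe sets, of which 0 were called, so its difference rests on 1 probe set. The probe set without a symbol and the double-symbol probe set fall outside the rule for named genes and were named after their values were seen. The count of reciprocal F1 hybrids was 2 to 4 when single arrays were left out, and 2 with RMA values, with MAS5 values, with quantile normalization and among probe sets with a mean of 8 or more.

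The comparison of C57BL/6J against C57BL/6ByJ asked what separates substrains that share most of their genome. Gabra2 was lower in C57BL/6J by 0.668 units (difference -0.668 ± 0.097, SE; 3 arrays against 2; adjusted p = 1.6e-05). Its other 3 bright probe sets differed by -0.564, -0.628 and -0.373 units. Erdr1 was higher in C57BL/6J by 1.40 ± 0.21 units, and Pisd-ps3 was lower (-1.25 ± 0.20). Wdfy1, an adaptor of endosomal receptor signalling, differed by -0.634 ± 0.101 units, and Pcsk4, a proprotein convertase of germ cells, by -0.522 ± 0.099.

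The other named genes differed less between the substrains. Apba1, a synaptic adaptor (0.50), Tanc2, a synaptic scaffold (0.41), Mnt, a MYC network repressor (0.33), Kif21b, a kinesin (0.32), Slco1a4, an organic anion carrier (0.32), Srgap1, a GTPase activator (0.28), and Sox13 (0.23) were higher in C57BL/6J. Slc25a30, a mitochondrial carrier (-0.50), Creg1 (-0.37), Pggt1b, a prenyltransferase subunit (-0.37), Czib (-0.25) and Cisd2, an iron-sulfur protein (-0.24), were lower. Nnt, the proton-pumping transhydrogenase, differed by -0.304 ± 0.075 units with an adjusted p of 0.0963. Of 14 named genes with further probe sets, 11 had none of them called the same way. The median ACTB 3'/5' ratio was 1.67 in C57BL/6J and 1.49 in C57BL/6ByJ.

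In limma's test 37 probe sets passed, 16 higher and 21 lower in C57BL/6J (43.24% higher), covering 18 genes. The count for C57BL/6J against C57BL/6ByJ was 11, 19, 18 or 19 without C57BL/6ByJ replicate 1, C57BL/6ByJ replicate 2, C57BL/6J replicate 2 or C57BL/6J replicate 3, and Pcsk4 and Pggt1b changed direction without C57BL/6ByJ replicate 1. Of the 17 named genes, 10 others lost their call without that array, and 13 lost it without C57BL/6ByJ replicate 2. With C57BL/6J replicate 1, 2 or 3 left out, 9, 11 or 10 lost it. Quantile normalization gave 64 calls (57.81% higher), rescaling to an SD of 2 gave 59 (55.93%), MAS5 values gave 66 with Pcsk4 and Pggt1b turned, the first residual component gave 72, and RMA values, with their mismatched C57BL/6J columns, gave 1522 (69.38%) with Gabra2, Wdfy1 and Pggt1b turned.

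The wild-derived against classical inbred strains comparison asked what separates CAST/EiJ, PWD/PhJ, PWK/PhJ and WSB/EiJ from 13 classical strains. Ntrk3, the receptor of neurotrophin-3, was higher in the wild-derived strains by 1.19 ± 0.18 PDNN units (SE; 4 strains against 13), and Hsf2, a heat shock transcription factor, was higher by 0.889 ± 0.049 (adjusted p = 2.9e-08). Rpn1, a subunit of the oligosaccharyltransferase, was lower (difference -1.60 ± 0.23 units). Ncan, a proteoglycan of the brain matrix, differed by -1.35 ± 0.27 units, and Taok1, a kinase acting on microtubules, by -1.35 ± 0.26.

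Further genes were higher in the wild-derived strains. These were Pisd-ps3 (1.02 units), Sox8, a transcription factor of glia (0.813), Khsrp, an RNA-binding protein (0.807), Slc43a2, an amino acid transporter (0.653), Otub1, a deubiquitinase (0.615), Hnrnpl, a splicing factor (0.606), Map1b, a microtubule protein (0.583), and Yme1l1, a mitochondrial protease (0.578). Lower were Reep3 (-1.11), Zfp267 (-1.04), Parm1 (-0.983), Garem1 (-0.928), Zyg11b (-0.887), Mff, a factor of mitochondrial fission (-0.880), and Dsp, the desmosomal protein desmoplakin and a dentate granule marker (-0.876). Of 19 named genes with further probe sets, 14 had none of them called the same way, among them Ntrk3 (0 of 7), Taok1 (0 of 6) and Ncan (0 of 2), so these differences rest on 1 probe set each. Whether sequence variants under the probes changed these signals was not tested.

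Myelin, astrocyte, endothelial, choroid plexus and ribosomal protein lists were lower as groups in camera's test with its preset correlation, and each lost its call with an estimated one. Mobp fell by 0.809 units as 1 of 11 myelin genes (1 when adjusted over the list alone), with adjusted p = 0.601 with an estimated correlation. Slc1a3, a glutamate transporter (-0.729), and Aqp4, a water channel (-0.349), fell as 2 of 10 astrocyte markers (also 2 over the list alone), with adjusted p = 0.185 with an estimated correlation. Abcb1a, an efflux pump (-0.261), fell as 1 of 9 endothelial markers (4 when adjusted over the list alone), and Kl (-0.737) as 1 of 10 choroid plexus markers (1 over the list alone), each with adjusted p = 0.601 with an estimated correlation. No ribosomal protein gene of 12 passed limma's test (2 lower when adjusted over the list alone, adjusted p = 0.601 with an estimated correlation), and the list's mean turned to 0.0278 in the RMA values without mismatched columns.

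Outside these lists, Man1a fell among pyramidal neuron markers (-0.442 units), Alad (-0.494) among known strain variants and Ndufv1, a subunit of complex I (-0.579), among respiratory chain genes, while Mx2, an interferon-response gene, rose by 0.105. Their lists did not pass. The mean, the median and the direction of the test differed in sign for the X inactivation, pyramidal neuron, thalamus, neurogenesis, GABA-A, glutamate receptor, and MHC and interferon lists. The median ACTB 3'/5' ratio was 2.32 in the wild-derived and 1.67 in the classical arrays, the RMA outlier share was 0.09 and 0.04, and the share of probe sets called present was 47.5% and 50.9%.

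Of 45037 probe sets 1777 passed limma's test, 878 higher and 899 lower (49.41% higher), covering 1199 genes. The count for wild-derived against classical inbred strains was 244 without PWD/PhJ (32.79% higher), 755 without CAST/EiJ (37.62%), 2992 without PWK/PhJ (73.8%) and 3219 without WSB/EiJ (49.05%). It was 634 without arrays with an RMA outlier share of 0.1 or more (39.27% higher), 880 among probe sets with a mean of 8 or more (20.68%), 764 with MAS5 values (25.26%), 970 with RMA values and 672 with RMA values without mismatched columns. Of the 20 named genes, 13 lost their call without PWD/PhJ, 7 without CAST/EiJ, 5 without PWK/PhJ and 1 without WSB/EiJ. Without the arrays with an RMA outlier share of 0.1 or more, 7 lost it.

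The later against earlier BXD strains comparison asked whether strain sets bred at different times from the same parents differ. Genes of the choroid plexus were higher in the later strains, with Clic6, a chloride channel protein, higher by 0.488 ± 0.126 PDNN units (SE; 39 strains against 29) and Kcnj13, a potassium channel, by 0.475 ± 0.113. Dbp, an output gene of the circadian clock, was higher by 0.332 ± 0.045 units, and Alad by 0.432 ± 0.064. Endothelial genes were lower, led by Cldn5, the tight junction protein of the blood-brain barrier, which fell by 0.234 ± 0.029 units (adjusted p = 6.1e-07). Frrs1l, an AMPA receptor auxiliary protein, differed by -0.402 ± 0.063 units.

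Of 9 endothelial genes 6 fell (8 when adjusted over the list alone), including Flt1 (-0.125 units) and Kdr (-0.0656), both receptors of vascular growth factor, and Tek (-0.0848), Cdh5 (-0.0699) and Esam (-0.0484). The endothelial list held its call with adjusted p = 0.00019 with an estimated correlation. Of 10 choroid plexus genes 5 rose (10 when adjusted over the list alone, adjusted p = 0.0142 with an estimated correlation), among them Aqp1, a water channel (0.278), Otx2, a transcription factor (0.198), and Slc4a5, a bicarbonate transporter (0.149). Of 11 microglia genes P2ry12, a purine receptor, fell by 0.198 units (3 when adjusted over the list alone, adjusted p = 0.044 with an estimated correlation). Of 10 thalamus genes Ramp3 rose by 0.0911 units (4 when adjusted over the list alone, adjusted p = 0.0142 with an estimated correlation).

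**Figure D3:**
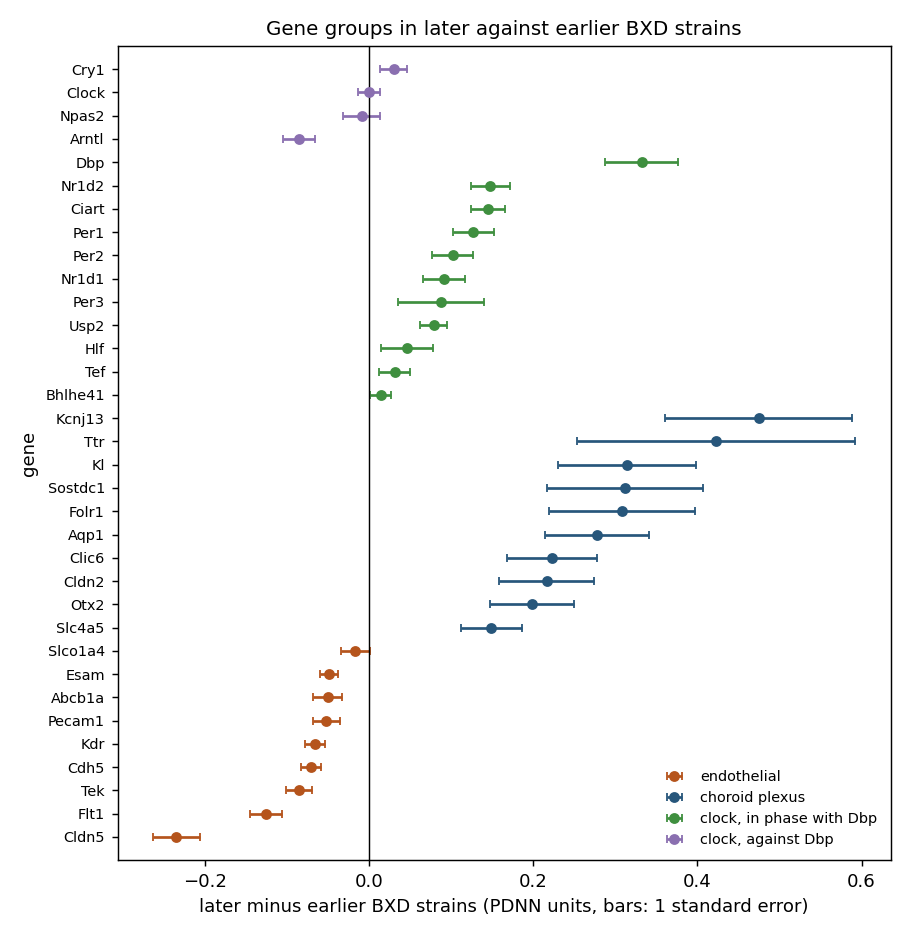
Later minus earlier BXD strains (x axis, PDNN units, bars of 1 standard error) for genes of the endothelial, choroid plexus and circadian clock lists (y axis). Endothelial genes run from -0.234 to -0.0163 units and choroid plexus genes from 0.149 to 0.475.

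Other genes higher in the later strains were Zic1, a transcription factor (0.287 units), F5, a coagulation factor (0.271), Slc4a2, an anion exchanger (0.245), Rdh5, a retinol dehydrogenase (0.244), and Hdhd3 (0.201). Lower were Epb41l4b (-0.296), Smc2os (-0.218), Dcn, a matrix proteoglycan (-0.213), Fabp7, a fatty acid binding protein of astrocytes (-0.202), the imprinted genes Nnat (-0.187) and Plagl1 (-0.170), and Syt17 (-0.167). Pdzd2, a dentate granule marker, rose by 0.157 units.

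The list of X inactivation and escape genes also passed camera's test (adjusted p = 0.0142 with an estimated correlation), with none of its 5 members past limma's test over all probe sets, 4395 of which had an unadjusted p under 0.05, and 1 higher when adjusted over the list alone. The myelin, MHC and interferon, respiratory chain and ribosomal protein lists passed with the preset correlation and no member past limma's test. Their calls were lost with adjusted p = 0.468, 0.452, 0.507 and 0.468 with an estimated correlation. The mean of the respiratory chain list turned to -0.0087 with MAS5 values and that of the ribosomal list to -0.0267 with MAS5 values and -0.00799 with RMA values without mismatched columns. The mean, the median and the direction of the test differed in sign for the pyramidal neuron, dentate granule, astrocyte, erythroid, neurogenesis and GABA-A lists.

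In total 280 probe sets passed limma's test, 172 higher and 108 lower in the later strains (61.43% higher), covering 223 genes with a median absolute difference of 0.0843 units. The median ACTB 3'/5' ratio was 1.32 in the later and 1.30 in the earlier arrays, and median age was 65 and 59 days. The count for later against earlier BXD strains was 119 with MAS5 values, 179 among probe sets with a mean of 8 or more (72.07% higher), 181 with the choroid plexus mean as a covariate (95 of them among the 280) and 498 with the first residual component (50.6% higher). It was 27453 of 45037 with the animal source as a covariate, where Clic6, Aqp1 and Rdh5 changed direction. Of the 280, 165 were among those calls, no larger a share than that of all probe sets. The second fit leaves out the error of the source term, which most later strains share. The count of 27453 therefore does not measure how many probe sets differ. Within the most frequent source, with 37 later strains and 2 earlier ones, the count was 8153 of 45037. Of the 280, 74 were among these.

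Males and females were compared across all strains. Eif2s3y, a translation initiation factor gene of the Y chromosome, was higher in males by 1.33 ± 0.03 PDNN units (SE; 98 male columns), Uty, a Y-linked histone demethylase gene, by 0.747 ± 0.026, and Kdm5d, another, by 0.726 ± 0.023. Xist, the RNA that silences an X chromosome in females, was lower in males (difference -1.95 ± 0.05 units). The X-linked genes Eif2s3x (-0.319 ± 0.036), Kdm6a (-0.180 ± 0.017), Ddx3x (-0.159 ± 0.027) and Kdm5c (-0.112 ± 0.012) were lower in males.

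All 3 Y-linked genes measured rose and all 5 genes of X inactivation and escape fell, over all probe sets and when adjusted over the list alone. Smaller differences were found for Rps4l (0.0827 units), Ddx4, a germ cell RNA helicase (0.0661), Ldoc1 (0.0552) and Cox7b2, a cytochrome oxidase subunit (0.0372), all higher in males. Erdr1 (-0.153), Pisd-ps3 (-0.129), C2cd5 (-0.0758) and Pbdc1 (-0.070) were lower. The MHC and interferon list was lower in males in camera's test (adjusted p = 0.000137, and adjusted p = 0.0329 with an estimated correlation), with none of its 11 members past limma's test over all probe sets or over the list alone. The immediate early list was higher (adjusted p = 0.0198) but lost its call with adjusted p = 0.76 with an estimated correlation, and none of its 12 genes passed either. The mean, the median and the direction of the test differed in sign for the known strain variant, interneuron, myelin, microglia and glutamate receptor lists.

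Limma's test of male against female gave 52 calls, 20 higher and 32 lower in males (38.46% higher), covering 17 genes, with 1788 probe sets at an unadjusted p under 0.05. Among probe sets with a mean of 8 or more there were 32 calls (21.88% higher). Fitted within panels, the calls numbered 47 in the BXD strains, 12 in the CXB strains and 18 in the inbred strains. The sex difference between panels passed limma's interaction test for Uty alone (adjusted p = 0.000191). Uty was higher in males by 0.744 ± 0.016 units in the BXD, 0.527 ± 0.043 in the CXB and 1.04 ± 0.09 in the inbred strains. That count of 1 became 0 with MAS5 values, with a mean of 8 or more and without arrays with an RMA outlier share of 0.1 or more, 3 with RMA values, and 5 without arrays whose headers disagree with the labels. Y-linked levels contradicted the labels of KK/HIJ replicate 2 (female) and PWD/PhJ replicate 1 (male), and both were among the inbred arrays fitted for Uty. All arrays of KK/HIJ carried the same labelled sex, as did those of PWD/PhJ. With strain in the model these arrays therefore bore on the sex difference only through the batch terms and the spread.

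The age of the pools was tested as a slope within the strain model. Zc3hav1, an antiviral zinc finger protein, was the single call of limma's test, with a slope of 0.0154 ± 0.0027 PDNN units per 10 days (adjusted p = 0.0074), among 1141 probe sets at an unadjusted p under 0.05. Of its 2 further probe sets 0 were called. Microglia genes fell with age as a list (adjusted p = 2.2e-08, and adjusted p = 0.0261 with an estimated correlation), with 0 of 11 members past the test and 2 when adjusted over the list alone. Neurogenesis genes of the dentate gyrus fell as a list (adjusted p = 0.000762, and adjusted p = 0.00345 with an estimated correlation), with 0 of 14 members past the test and 1 over the list alone. The MHC and interferon list rose (adjusted p = 0.000193, and adjusted p = 0.0393 with an estimated correlation), with no member of 11 past either test. The slope uses age differences between pools of the same strain, and the widest were those of BXD19, BXD22 and BXD74. In BXD19 and BXD22 the older pool also had another labelled animal source. The list tests were not repeated without pools older than 100 days.

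The pyramidal neuron, dentate granule and myelin lists were lower with age and the choroid plexus list higher in camera's test with its preset correlation. Their calls were lost with adjusted p = 0.297, 0.137, 0.27 and 0.316 with an estimated correlation, and no member passed limma's test over all probe sets or over the list alone. The mean and the direction of the test differed in sign for the immediate early list. Across the 5 comparisons and 20 lists, 29 of 100 list tests passed with the preset correlation and 14 with an estimated one. The age slope of Zc3hav1 was no longer called with RMA, MAS5, quantile-normalized or rescaled values or without pools older than 100 days, settings that each gave 0 calls by limma. With a mean of 7.65 units, Zc3hav1 lay outside the filter on a mean of 8 or more, which also gave 0.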

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

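Tests chosen only after the result was seen were the 4-component and sequence-variant tests of the parental calls, the clock gene test, taken up once Dbp, Ciart and Nr1d2 had been seen, and the tests of the father's allele and of sex for Snhg14, and the settings with residual components or the choroid plexus mean as covariates or with strains of 1 source were added after seeing the data.

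Genes called higher in DBA/2J than in C57BL/6J, such as Gas7, Sfpq and Gsk3b, seldom varied between BXD strains (16.7% against 62.59% of the calls lower in DBA/2J). Sequence variants under the probes would segregate among BXD strains, so the pattern itself argues against them as its whole cause, also for large differences: of probe sets higher by over 0.6 units 17.79% were BXD calls (100 of 562), against 80.95% of those lower by over 0.6 (85 of 105). The first component of the variation within BXD strains did not by itself account for the pattern, since 100% of the 1726 calls higher in DBA/2J without a BXD call stayed called with it as a covariate, at a median size of 0.425 units against 0.432. Of these probe sets 71.38% shared a sign on the component, a share between the bounds set for and against it, so a smaller part in the pattern stays open. With the first 4 components 12.17% of them stayed called, their median size falling from 0.432 to 0.136 units, by more than the SEs of 0.112 and 0.0828, while 75.11% of the calls shared with the BXD panel stayed and their median size went from 0.354 to 0.289. Variation among arrays, as in components 3 (led by Sfpq) and 4 (led by Ttr), may therefore underlie much of this set, although a parental difference in those transcripts stays open.

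In the later BXD strains, endothelial genes were lower and choroid plexus and clock genes higher. More choroid plexus in the dissected tissue did not account for the endothelial genes, whose mean difference kept 101.9% of its size with the choroid plexus mean as a covariate (5 of 9 genes called, against 6 without it), although only 95 of the 280 calls were called with it. Unequal shares of parental alleles cannot be told apart from other differences between the strain sets. Of the calls 11.79% (33 of 280, 20.26 by chance) were also parental calls, but the parental comparison recovered 28.4% of simulated differences of 0.2 units, and of 13 neighbouring genes with a call, 11 of them BXD strain effects, 5 were parental calls, so a low share excludes little. Clock genes that peak with Dbp exceeded those that peak against it by 0.0958 units in the median, more than in 100% of 10000 random lists. Random lists do not carry the correlation that clock genes may share, so this percentage does not measure the strength of the evidence. Time of day at collection may contribute, but the test does not settle it. Of 11 genes in phase 6 were called higher, and Arntl, of the 4 in antiphase, was lower (-0.0851). Without Dbp, Ciart and Nr1d2, seen before the test, the difference was 0.0873 units. Breeding and housing source cannot be told apart from the strain sets, because the most frequent source held 37 of 39 later and 2 of 29 earlier strains. With source as a covariate, estimable through 14 of 68 strains, the count was 27453 of 45037. The 165 of the 280 among them were no larger a share than that of all probe sets. The fit between strains leaves out the error of the source term, so that count decides nothing.

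Snhg14 and 2 transcripts named with it were higher in D2B6F1 than in B6D2F1. The sex of the arrays did not account for this, as the largest difference between the sexes in the BXD panel was 0.854% of the F1 difference. For Snhg14 a mislabelled D2B6F1 array did not either, since 107.9% of its difference was left without replicate 1. The other 2 transcripts were not part of that test. Expression of the father's allele alone cannot be told apart from other parent-of-origin effects here: both F1s lay within 2 SE of their fathers at the other probe sets, but at Snhg14 B6D2F1 lay 3.11 SE below DBA/2J, the largest distance (-0.781 ± 0.251 units), outside rather than between the parents. That distance rests on single arrays. It was 1.59, 1.97 or 1.92 SE without B6D2F1 replicate 1, B6D2F1 replicate 2 or DBA/2J replicate 1, and 4.26 or 3.20 SE without B6D2F1 replicate 3 or DBA/2J replicate 2, and the averaged B6D2F1 arrays, replicates 2 and 3, were at 7.68 and 8.69 units. Expression of the father's allele alone stays a hypothesis, found and tested on the same data.

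At 5 of 20 genes named between wild-derived and classical strains, WSB/EiJ stood apart from the other 3 wild-derived strains by a gap over range above Dixon's critical value for 4 values. Chance passes about 1 in 20 groups, but these genes were chosen for large differences and share the same 4 strains, so no count to be had by chance can be given. WSB/EiJ was at 7.68 units for Sox8 against 8.72 to 8.92 in the others (gap over range 0.834) and at 9.81 for Rpn1 against 7.88 to 7.98 (0.95). It was at 9.48 for Taok1 against 8.04 to 8.24 (0.859), at 9.33 for Parm1 against 7.64 to 7.81 (0.902), and at 8.07 for Zyg11b against 7.15 to 7.27 (0.874). The means of the 13 classical strains were 7.70 (Sox8), 9.99 (Rpn1), 9.80 (Taok1), 9.09 (Parm1) and 8.31 (Zyg11b). At all 5 genes WSB/EiJ lay nearer the classical mean than the other wild-derived strains did. The differences from the classical strains at these genes thus rested on the other 3. For Uty, the difference between males and females differed between panels by limma's interaction test (adjusted p = 0.000191), at 0.744 units in BXD, 0.527 in CXB and 1.04 in inbred strains. Y-linked levels contradicted the labelled sex of KK/HIJ replicate 2 and PWD/PhJ replicate 1, which are among the inbred arrays.

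Against random splits of the same strains or arrays, taken as independent, the real split gave the most calls in 3 comparisons. Of 100 splits, 1 gave as many calls as wild-derived against classical (1777, highest other 5), 1 as many as later against earlier BXD strains (280, highest other 11) and 1 as many as male against female (52, highest other 1). Of the wild-derived strains, PWD/PhJ and PWK/PhJ were much alike. PWD/PhJ replicate 2 correlated across probe sets with PWK/PhJ replicates 1 and 2 at 0.924 and 0.889, against 0.927 within PWD/PhJ. The splits do not allow for such likeness between strains, so they cannot by themselves exclude chance for the wild-derived count. For the sex difference between panels 3 of 100 splits gave as many calls as the real 1, and the highest other was 1 as well. That share is under 0.05, but the count became 0 with MAS5 values, with a mean of 8 or more and without arrays with an RMA outlier share of 0.1 or more, so this single call stays uncertain.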

How the results depend on the processing

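Settings chosen only after seeing the data were the removal of arrays with disagreeing headers, rescaling, the residual components, RMA without mismatched columns, 1 source alone and the choroid plexus covariate. Of 1937 values of named genes and lists under alternatives, 1665 kept their direction and side of the threshold, 258 kept their direction without passing and 14 reversed. Part of these could not change by construction. The series value table held the same scores, strain effects have no direction to reverse, and lists keep their direction under an estimated correlation. The count of 1665 therefore overstates how often results held. The parental share of BXD spread stayed between 0.467 and 0.505. Except where fewer probe sets or samples, or RMA columns that match other arrays, set the count by construction, the cause was not tested. No paired analysis was possible because replicate numbers only name arrays in order and strain is already in the model. Array number and signal over background limit small differences.

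RMA values gave 2016 calls for DBA/2J against C57BL/6J, 162 for F1 hybrids against the mid-parent, 1522 for C57BL/6J against C57BL/6ByJ, 970 for wild-derived against classical inbred strains, 3 for the sex difference between panels and 0 for the age slope. Without mismatched columns RMA gave 672, 2 and 0 for the last 3. RMA reversed, between DBA/2J and C57BL/6J, Phgdh (0.269), Pttg1 (0.55), Prune2 (0.429) and Rpgrip1 (0.592), and, between the C57BL/6 substrains, Gabra2 (0.366), Wdfy1 (0.417) and Pggt1b (0.217). MAS5 values gave 1 for the mid-parent, 66 for the substrains, 764 for wild-derived, 119 for later against earlier BXD strains, 0 for the sex difference between panels, 0 for age, 2458 for the BXD and 212 for the CXB strain effect, and reversed Pcsk4 (0.0277) and Pggt1b (0.399).

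A mean of 8 or more gave 2130 (DBA/2J), 880 (wild-derived), 179 (later), 32 (male against female), 0 (sex between panels), 0 (age), 2260 (BXD) and 315 (CXB). Quantile normalization gave 4 (mid-parent), 64 (substrains) and 0 (age). Rescaling gave 5, 59 and 0 for these. Without arrays of outlier share 0.1 or more there were 634 (wild-derived), 0 (sex between panels), 3 (age) and 172 (CXB). No batch term gave 1480 (DBA/2J) and 2 (age), no pools over 100 days 0 (age), and no arrays with disagreeing headers 3 (mid-parent), 5 (sex between panels) and 2 (age). The first residual component gave 4995 (DBA/2J), 72 (substrains) and 498 (later). Separate duplicates gave 2 (mid-parent), and spread from inbred strains and F1 hybrids alone 880 (DBA/2J). The animal source gave 27453 (later) and reversed Clic6 (-0.0479), Aqp1 (-0.026) and Rdh5 (-0.0103), 1 source alone gave 8153, and the choroid plexus mean 181. An estimated correlation left 14 of 29 list calls.

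Leaving out 1 array gave 1429 to 3368 calls for DBA/2J, 0 to 3 for the mid-parent, 2 to 4 for the reciprocal F1 hybrids and 11 to 32 for the substrains. Pcsk4, C57BL/6J against C57BL/6ByJ, ran from -1.03 to 0.0452 and Pggt1b, C57BL/6J against C57BL/6ByJ, from -0.764 to 0.0753, both reversed without C57BL/6ByJ replicate 1. One array less gave 248 to 332 for later, 50 to 53 for male against female, 1 to 2 for age, 3593 to 4031 for BXD and 353 to 620 for CXB. Leaving out 1 strain gave 244 to 3219 for wild-derived. The lowest counts came without DBA/2J replicate 1, C57BL/6ByJ replicate 1 and PWD/PhJ.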

Other observations

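The tests of clock genes, neighbouring genes, imprinted genes and array identity given here were chosen after the calls had been seen. Ciart, a repressor of the clock, was higher in the later strains by 0.145 ± 0.020 PDNN units, Nr1d2, a nuclear receptor of the clock, by 0.148 ± 0.024, Per1 by 0.127 ± 0.025, Per2 by 0.102 ± 0.025 and Usp2, a deubiquitinase with a daily rhythm, by 0.079 ± 0.017, all past limma's test. Arntl, the activator in antiphase, fell by 0.0851 ± 0.0195 units, while Cry1, Clock and Npas2 differed by 0.0303 ± 0.0161, 0.000452 ± 0.0134 and -0.00843 ± 0.0225 and did not pass. Nr1d1 differed by 0.0918 ± 0.0255 (adjusted p = 0.0693), and Per3, Hlf, Tef and Bhlhe41 did not pass either.

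Calls between later and earlier BXD strains also gathered among neighbouring genes. In the gene order of the reference annotation, 13 of 222 called genes lay within a window of 100 measured genes, and the highest of 1000 random draws was 10 with a median of 6. These genes were Rnf20, Smc2os, Rad23b, Frrs1l, Epb41l4b, Slc31a1, a copper transporter, Hdhd3, Alad, Pole3, Atp6v1g1, a subunit of the proton pump, Tnc, a matrix protein, Ptprd and Mpdz. Of the 13, 11 were BXD strain effects. The random draws do not carry the shared inheritance of neighbouring genes in these strains. They therefore do not measure how far the gathering exceeds chance, and the 13 genes may not be separate findings. The 5 with a parental call, Smc2os, Rad23b and Frrs1l lower and Hdhd3 and Alad higher in DBA/2J, had the same sign in the later strains. Of 20 genes known to be imprinted, Snhg14 was the single call between the F1 hybrids (1 at an unadjusted p under 0.05, 1 when adjusted over the list alone). Peg3 differed by 0.00138 ± 0.0932 units, Ndn by -0.018 ± 0.101 and Nnat by -0.317 ± 0.184. The total level of an imprinted gene differs between these hybrids only where the parental alleles differ in level. Small differences here therefore do not exclude parent-of-origin expression.

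Arrays were compared over 254 probe sets chosen for a wide spread and a high intraclass correlation between the labelled BXD strains. This choice favours matches within a labelled strain, so the count of matches is partly built in. The array most similar to each of 131 BXD arrays was of its own strain for 129. The exceptions were BXD14 replicate 1 and BXD23 replicate 1, but all 4 arrays of these strains resembled each other. BXD23 replicate 1 correlated across probe sets with BXD14 replicates 1 and 2 at 0.940 and 0.937 and BXD23 replicate 2 at 0.820 and 0.8325, against 0.939 within BXD14 and 0.834 within BXD23. On a scale over 144 probe sets with C57BL/6J at 0 and DBA/2J at 1, D2B6F1 replicate 1 lay at 0.667 and the other F1 arrays at 0.365 to 0.435. Over the 254 probe sets the arrays most similar to D2B6F1 replicate 1 were BXD51 replicates 1 and 2 (correlation across probe sets 0.737 and 0.690) and DBA/2J replicate 1 (0.5825), while its correlation with D2B6F1 replicates 2 and 3 was -0.0596 and -0.0487. Those replicates correlated with each other at 0.664. They also correlated with B6D2F1 replicate 3, an array of the averaged pair, at 0.549 and 0.490. With B6D2F1 replicates 1 and 2 their correlations ran from -0.117 to 0.0225.

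On a scale of 3 Y-linked genes, 3 of 200 arrays lay past the midpoint of 0.5 for their labelled sex. These were D2B6F1 replicate 1, labelled female (0.612), KK/HIJ replicate 2, labelled female (0.887), and PWD/PhJ replicate 1, labelled male (0.129). BXD9 replicate 2, labelled as mixed, had an Eif2s3y value of 7.34 units, where females ran from 7.14 to 7.83 and males from 7.93 to 9.57, and an Xist value of 8.25, where females ran from 8.44 to 10.3 and males from 7.18 to 7.62. Among the 197 RMA columns, 4 did not match the PDNN array of the same name, and the others correlated with theirs at 0.914 or more. The 3 columns headed C57BL/6J correlated with their own arrays at -0.259, -0.0816 and -0.277 and with BALB/cJ replicates 1, 2 and 3 at 0.944, 0.962 and 0.958. The column headed BXD14 replicate 2 correlated with its own array at 0.00198.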
